A study of Homo sapiens with 12 samples.

How the data were processed

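Poly(A) RNA was sequenced from SHEP cells, a human neuroblastoma line, that carried a MYCN-ER fusion activated by 4-hydroxytamoxifen (OHT, 200 nM) and a doxycycline-inducible (Dox, 1 µg/ml) short hairpin RNA against TCEAL1, per the labels' protocols. Total RNA was extracted, treated with DNase on the column and enriched for poly(A) RNA, and strand-specific libraries were made with the NEBNext Ultra II Directional kit, per the same protocols. The 12 libraries fall into 4 groups of 3, named here Ctrl (neither compound), OHT, Dox and OHT_Dox (both compounds). The labels give replicate numbers but do not say whether replicates were separate cultures, and they give no treatment times.

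The deposited values are CPM, read counts scaled to a total of 1000000 per library, for 28576 genes with Ensembl identifiers. The unit is that of the deposited table's name, and each library sums to 1000000 over the genes listed. The submitters' processing notes name DRAGEN, FastQC, Bowtie2, STAR, Bowtie and featureCounts and the builds hg19 and mm10 for RNA-seq and ChIP-seq together, without saying which tool made which file, its version, the gene annotation or the strand setting of the counting. Every value was a whole multiple of 1 step per library within a tolerance of 0.01 reads, so whole read counts were recovered from the deposited CPM. They came to between 44466458 and 57694970 reads per library. The table holds no gene with a total below 13 reads over the 12 libraries and no gene encoded on the mitochondrial genome, 6873 of its genes have no symbol, and 8 symbols are used more than once.

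Identifiers were matched to GENCODE release 29 (28572 matched), which was used only for names, transcript length, GC content, 3′ untranslated regions and neighbouring genes. No coordinates are given, because the build named in the notes and that of the annotation differ. Genes that overlap, share near-identical copies or lie antisense to another gene are uncertain, since the strand setting is not stated.

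Genes with a CPM of at least 0.5 in at least 3 libraries were tested (18674 genes). Values were transformed to log2(CPM + 0.5) and fitted with limma 3.58.1 in R 4.3.3 with 1 mean for each of the 4 groups, 1 shared estimate of the spread and empirical Bayes moderation with a mean trend. Fold changes and their standard errors (SE) are on that log2 scale, and the pseudocount of 0.5 draws the fold changes of genes at a few CPM towards 0. The 5 contrasts were OHT against Ctrl, OHT_Dox against Dox, Dox against Ctrl, OHT_Dox against OHT, and the interaction (OHT_Dox minus Dox) minus (OHT minus Ctrl). P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast, a call was an adjusted p below 0.05, and the tests are two-sided. These p-values measure the spread between these 12 libraries only.

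The design, the gene lists, the rule for named genes and most other settings were fixed before the data were examined. The rule names TCEAL1, USP11, USP7, TCEA1 and MYCN first, then the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and with every library of the one group above or below every library of the other. Genes known only by clone names, LOC or LINC symbols were left out, and 2 to 4 members with the smallest p were named for each list described.

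The 26 lists were nucleolar and ribosome biogenesis genes, nucleotide and polyamine synthesis genes, DNA replication genes, mitotic genes, genes described as MYC-repressed, cytosolic ribosomal protein genes, cholesterol synthesis and uptake genes, amino acid response and ATF4 target genes, mitochondrially encoded genes, endoplasmic reticulum stress genes, heat shock genes, p53 target genes, interferon-stimulated genes, inflammatory and NF-kB target genes, immediate early genes, YAP and TEAD target genes, TGF-beta response genes, extracellular matrix genes, hypoxia and glycolysis genes, replication-dependent histone genes, RNA polymerase II subunit genes, pausing and elongation factor genes, TCEAL and BEX family genes, adrenergic and mesenchymal neuroblastoma markers, and epithelial and haematopoietic markers. The mitochondrially encoded list had 0 of its 13 members in the table and was not tested. Each of the other lists was tested against all other genes with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation. Each was also tested with fry, which asks whether the members changed without setting them against other genes. P-values were adjusted over the lists within a contrast. Members were also called with p-values adjusted over the list alone.

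The size of a response in 1 background relative to the other was taken as the slope of a Deming regression with equal errors across genes called for the mean effect over both backgrounds, a choice that favours neither. Its 95% interval came from refits without each library in turn (jackknife). For the seed scan, 7-base words were counted in the 3′ untranslated regions (at least 50 bases) of 12160 genes with a mean log2 value above 1, and the Dox effects were first adjusted for the length and GC content of the region and of the transcript and for expression. The 16319 words present in at least 50 genes were scanned against a Bonferroni limit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.

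The steps were tested on simulated reads for the same 18674 genes with 200 genes changed. At a true change of 1.5-fold the test recovered 66% of them for OHT without Dox, 74.5% for OHT with Dox, 70.5% for Dox without OHT, 71% for Dox with OHT and 56.5% for the interaction. At 1.25-fold it recovered 28%, 24.5%, 27%, 27% and 4.5% in the same order. False calls made up 18.2% of the interaction calls at 1.25-fold (2 beside 9 recovered), 7.38% at 1.5-fold and 6.47% at 2-fold. In the other comparisons they made up 0% to 7.29%. The simulated genes were drawn independently, without trends of a library with transcript length or GC content. Simulated slopes of 0.5, 0.8 and 1 were estimated as 0.512, 0.804 and 1.00.

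The other settings fixed in advance were pseudocounts of 0.1 and 1, no filter and a filter of 1 CPM, trimmed-mean rescaling of the libraries, the replicate number as a block, robust moderation, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, a fit of only the groups compared, each library left out, the ratio of medians in place of the slope, and the estimated correlation for the lists. Settings chosen after the data were seen were removal of each library's trend with transcript length and GC content, a pair of libraries left out together, in 2 versions, the MIR30A host genes left out of the Dox slope, and the genes with 1 particular word in the 3′ untranslated region left out.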

Results

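The data are poly(A) RNA-seq profiles of SHEP neuroblastoma cells in which OHT activates a MYCN-ER fusion protein and Dox induces a short hairpin RNA against TCEAL1, a gene of the transcription elongation factor A-like family. The series title names TCEAL1 together with the deubiquitinases USP11 and USP7. The 12 libraries form 4 groups of 3 (Ctrl, OHT, Dox and OHT_Dox), with between 44466458 reads (OHT_Dox replicate 3) and 57694970 reads (Ctrl replicate 3) per library. Values are CPM as deposited, given as mean ± SD with n = 3 per group, and changes are log2 fold changes ± SE on the log2(CPM + 0.5) scale from limma. All 12 libraries entered 1 fit of the 4 groups. List tests are those of camera with a preset correlation of 0.01 unless an estimated correlation is named.

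TCEAL1 (ENSG00000172465), the gene the hairpin targets, was lower in each of the 6 libraries with Dox than in each of the 6 without. It stood at 9.71, 9.11 and 10.7 CPM in Ctrl, 8.23, 9.75 and 8.99 CPM in OHT, 2.62, 2.54 and 2.74 CPM in Dox and 2.58, 2.50 and 1.73 CPM in OHT_Dox. With Dox it fell by -1.72 ± 0.13 without OHT (adjusted p = 1.52e-07) and by -1.79 ± 0.13 with OHT (adjusted p = 7.80e-08). Its change with OHT did not pass the test in either background. USP11 (ENSG00000102226) went from 124 ± 2.1 CPM in Ctrl to 101 ± 6.7 CPM with OHT, a change of -0.30 ± 0.06 (adjusted p = 8.39e-04). In the presence of Dox its change with OHT was -0.16 ± 0.06 (adjusted p = 0.0580), and the difference between these changes did not pass the test (interaction 0.15 ± 0.08, adjusted p = 0.400). Its libraries lay between 113 and 124 CPM in Dox and between 101 and 110 CPM in OHT_Dox. USP7 (ENSG00000187555) lay between 157 ± 12 CPM in Ctrl and 169 ± 6.3 CPM in OHT_Dox. TCEA1 (ENSG00000187735), which encodes the elongation factor TFIIS, lay between 159.9 ± 9.9 CPM in OHT_Dox and 169 ± 7.0 CPM in OHT. Neither passed the test in any comparison.

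MYCN (ENSG00000134323), whose reads can come from the fusion and from the endogenous gene alike, was abundant in every group, at 496 ± 69 CPM in Ctrl, 536 ± 94 CPM in OHT, 538 ± 25 CPM in Dox and 425 ± 47 CPM in OHT_Dox. Its single libraries lay at 644, 492 and 471 CPM in OHT and at 429, 376 and 470 CPM in OHT_Dox. With OHT it changed by 0.11 ± 0.10 without Dox (adjusted p = 0.518) and fell by -0.34 ± 0.10 with Dox (adjusted p = 0.0191). The fall was not called without Dox replicate 3 (-0.31) or without OHT_Dox replicate 2 (-0.26), nor by DESeq2 (-0.31). The interaction of MYCN was -0.45 ± 0.15 (adjusted p = 0.221), and it was called without Ctrl replicate 1 (-0.56).

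**Figure D1:**
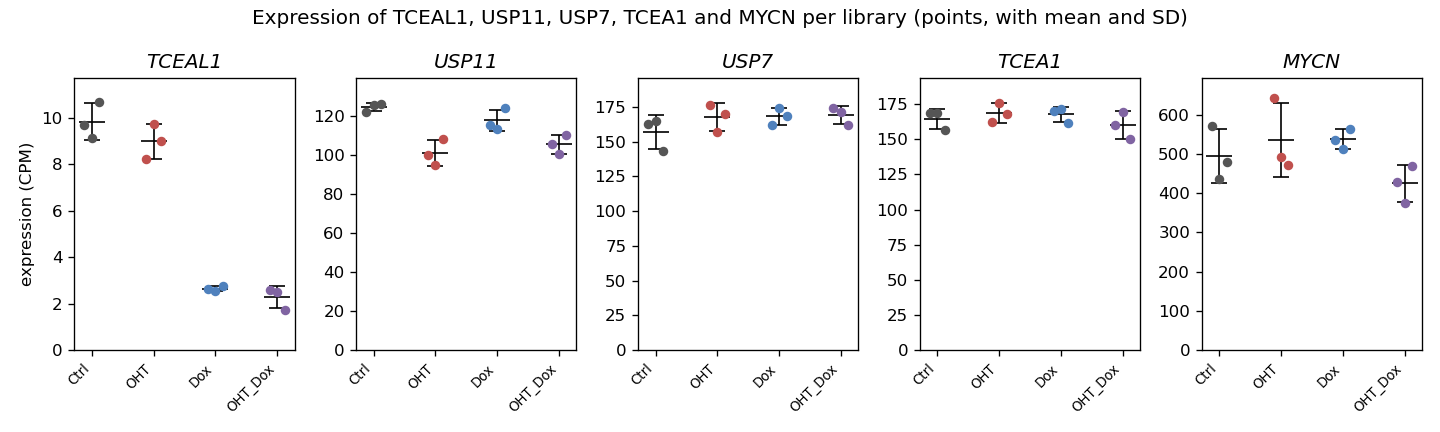
Expression of TCEAL1, USP11, USP7, TCEA1 and MYCN in CPM on the y axis for each library (points), with the mean and SD of the 3 libraries of each group (bars) along the x axis. TCEAL1 lies between 8.23 and 10.7 CPM in the libraries without Dox and between 1.73 and 2.74 CPM in those with Dox.

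The comparison of OHT with Ctrl asks what OHT does in cells with MYCN-ER while TCEAL1 is at its usual level. Every library carries the fusion, so effects of OHT itself are not separated from those of MYCN-ER. SH2B2 (ENSG00000160999), an adaptor of receptor signalling, rose from 1.11 ± 0.28 to 8.91 ± 0.43 CPM (2.56 ± 0.16). NR1D1 (ENSG00000126368), a nuclear receptor of the circadian clock, rose from 2.98 ± 0.70 to 19.6 ± 0.87 CPM (2.55 ± 0.17). PLD6 (ENSG00000179598) rose from 27.2 ± 1.2 to 113 ± 8.5 CPM (2.04 ± 0.07, adjusted p = 1.27e-13). SLC6A15 (ENSG00000072041), an amino acid transporter, rose from 14.3 ± 0.75 to 57.6 ± 4.3 CPM (1.98 ± 0.07). MYC (ENSG00000136997), a paralogue of MYCN, fell from 29.97 ± 0.093 to 10.99 ± 1.1 CPM (-1.41 ± 0.10, adjusted p = 3.96e-09). ANKRD1 (ENSG00000148677), a YAP target, fell from 700.3 ± 67 to 342 ± 28 CPM (-1.03 ± 0.07). In total 2357 genes rose and 1641 fell, 3998 of 18674 (21.4%), and 109 rises and 6 falls exceeded 2-fold. After each library's trend with transcript length and GC content was removed, a step chosen after the data were seen, 2434 rose and 2520 fell. The other large rises were SLC19A3 (2.22 ± 0.11), TRIB1 (2.21 ± 0.13), GPR157 (2.06 ± 0.08), LRFN1 (2.04 ± 0.11), BHLHE41 (1.93 ± 0.12) and TSC22D3 (1.91 ± 0.13). The other large falls were the cytokine genes CXCL1 (-1.65 ± 0.14), IL11 (-1.40 ± 0.16) and CXCL8 (-0.95 ± 0.17), the hyaluronan synthase HAS2 (-1.01 ± 0.15), ZFP36 (-0.92 ± 0.13), SLFN5 (-0.92 ± 0.12), SNHG25 (-0.89 ± 0.14) and the kinetochore gene DSN1 (-0.86 ± 0.06). By the rule that chose them, each of these 20 genes had all 3 libraries of one group beyond all 3 of the other.

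Growth-related lists did not all move the same way with OHT. Of 29 nucleolar and ribosome biogenesis genes, 12 rose and 0 fell (17 and 0 over the list alone), led by NOLC1 (0.56 ± 0.05), POLR1B (0.62 ± 0.06) and POLR1A (0.58 ± 0.07). It had adjusted p = 1.02e-06, and adjusted p = 0.115 with an estimated correlation. Of 49 cytosolic ribosomal protein genes, 0 rose and 12 fell (0 and 15 over the list alone), among them RPS20 (-0.25 ± 0.06) and RPS12 (-0.28 ± 0.07). These falls came to 7 after rescaling and 11 after removal of the length and GC trend. The list had adjusted p = 2.60e-07, and adjusted p = 0.378 with an estimated correlation. Of 21 nucleotide and polyamine synthesis genes, 7 rose and 2 fell (7 and 3 over the list alone), including IMPDH1 (0.73 ± 0.06), PPAT (0.78 ± 0.07) and ODC1 (0.48 ± 0.07), and the list did not pass the test (adjusted p = 0.0552). Of 23 DNA replication genes, 2 rose and 12 fell (2 and 12 over the list alone), with ORC1 at -0.44 ± 0.07 and CDC6 at -0.30 ± 0.06. The list had adjusted p = 0.00101, and adjusted p = 0.115 with an estimated correlation. Of 22 mitotic genes, 1 rose and 11 fell (1 and 13 over the list alone), with CCNB2 at -0.29 ± 0.06 and CDK1 at -0.34 ± 0.07. Its test gave adjusted p = 7.57e-05, and adjusted p = 0.191 with an estimated correlation. Of 21 cholesterol genes, 7 rose and 0 fell (8 and 0 over the list alone), with SQLE at 0.61 ± 0.06 and DHCR7 at 1.05 ± 0.16. As a list it had adjusted p = 0.0106, and adjusted p = 0.484 with an estimated correlation.

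Part of the immediate early and inflammatory lists fell with OHT. Of 24 immediate early genes, 2 rose and 10 fell (2 and 10 over the list alone), including KLF6 (-0.66 ± 0.07), DUSP6 (-0.80 ± 0.10) and IER5 (-0.58 ± 0.08). Its test gave adjusted p = 3.29e-04, and adjusted p = 0.115 with an estimated correlation. Of 16 inflammatory and NF-kB target genes, 2 rose and 5 fell (2 and 8 over the list alone). As a list it had adjusted p = 0.0106, and adjusted p = 0.222 with an estimated correlation. CXCL2 (-0.95 ± 0.19) fell beside CXCL1 and CXCL8, and SOD2 (0.33 ± 0.05) rose. The endoplasmic reticulum stress list, of which 0 rose and 3 fell (0 and 3 over the list alone) among 16 members, was led by HERPUD1 (-0.32 ± 0.07) and passed with adjusted p = 0.0417, and adjusted p = 0.303 with an estimated correlation. The histone list, of which 0 rose and 0 fell (0 and 0 over the list alone) among 12 members, had H2AC11 at -0.32 ± 0.12 and passed with adjusted p = 0.0160, and adjusted p = 0.115 with an estimated correlation. The TCEAL and BEX family list, of which 0 rose and 3 fell (0 and 3 over the list alone) among 6 members, passed at adjusted p = 0.0479, not after rescaling of the libraries (adjusted p = 0.0526), and stood at adjusted p = 0.303 with an estimated correlation. Its member TCEAL9 changed by -0.56 ± 0.08 and TCEAL8 by -0.35 ± 0.08.

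The remaining lists did not pass the test for OHT without Dox, though each had members that did. The counts of rises and falls were 2 and 6 (2 and 6 over the list alone) of 18 YAP and TEAD targets, where CCN2 fell (-0.58 ± 0.05) and FJX1 rose (0.33 ± 0.07). There were 7 and 3 (7 and 3 over the list alone) of 22 amino acid response and ATF4 targets, where the transporter SLC7A5 rose (1.09 ± 0.06) and SESN2 fell (-0.72 ± 0.11). They were 5 and 2 (5 and 2 over the list alone) of 22 hypoxia and glycolysis genes, where HK2 (1.09 ± 0.06) and PDK1 (0.88 ± 0.08) rose and SLC2A3 fell (-0.75 ± 0.09). There were 4 and 4 (5 and 4 over the list alone) of 21 p53 targets, where GDF15 fell (-0.65 ± 0.10) and ZMAT3 rose (0.45 ± 0.09). They were 1 and 3 (1 and 3 over the list alone) of 12 genes described as MYC-repressed, where GADD45A fell (-0.67 ± 0.10) and CEBPD rose (0.69 ± 0.11). There were 3 and 5 (3 and 5 over the list alone) of 20 TGF-beta response genes and 1 and 1 (1 and 1 over the list alone) of 25 extracellular matrix genes. Of 20 interferon-stimulated genes 0 and 3 (0 and 3 over the list alone) rose and fell, with IFIT1 at -0.51 ± 0.10. Of 37 pausing and elongation factor genes 3 and 7 (5 and 8 over the list alone), with GTF2F1 at -0.28 ± 0.06 and NELFA at 0.31 ± 0.08. The counts were 1 and 2 (1 and 2 over the list alone) of 12 RNA polymerase II subunit genes, 1 and 0 (0 and 0 over the list alone) of 11 heat shock genes, 2 and 0 (2 and 1 over the list alone) of 7 adrenergic markers. There were 7 and 2 (7 and 4 over the list alone) of 22 mesenchymal markers with PRRX1 at 0.68 ± 0.06, and 0 and 2 (0 and 2 over the list alone) of 5 epithelial and haematopoietic markers with KRT18 at -0.17 ± 0.05. The preset p-values of these lists ran from adjusted p = 0.05003 for YAP and TEAD targets to adjusted p = 0.990 for p53 targets. Median, mean and test differed in sign for the ATF4, p53 and adrenergic lists, and the medians of the p53 and mesenchymal lists changed sign on rescaling.

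The comparison of OHT_Dox with Dox asks the same of cells in which the hairpin was induced. SH2B2 rose from 0.946 ± 0.32 to 11.03 ± 1.6 CPM (3.01 ± 0.16, adjusted p = 2.52e-10), NR1D1 by 2.36 ± 0.17, PLD6 by 1.89 ± 0.07 and SLC6A15 by 1.84 ± 0.07. MYC fell from 21.9 ± 2.0 to 6.59 ± 0.70 CPM (-1.66 ± 0.10, adjusted p = 6.61e-10), and RGS4 (ENSG00000117152), a regulator of G protein signalling, from 96.5 ± 13 to 48.3 ± 1.7 CPM (-0.98 ± 0.08). In total 2153 genes rose and 2709 fell, 4862 of 18674 (26.04%), and 94 rises and 13 falls exceeded 2-fold. The excess of falls turned under other scalings, with 2469 rises and 2308 falls after trimmed-mean rescaling, 2541 and 2194 with edgeR, and 2624 and 2453 with DESeq2. The other large rises were TRIB1 (2.32 ± 0.13), GPR157 (2.09 ± 0.08), SLC19A3 (2.09 ± 0.11), BHLHE41 (1.93 ± 0.12), ZNF469 (1.92 ± 0.10, ENSG00000225614) and MMP17 (1.83 ± 0.12, ENSG00000198598). The other large falls were CXCL1 (-1.38 ± 0.14), HAS2 (-1.38 ± 0.15), IL11 (-1.24 ± 0.16), CXCL8 (-1.22 ± 0.17), SLFN5 (-1.18 ± 0.12), OR51B4 (-1.07 ± 0.13), ARRDC3 (-1.05 ± 0.14) and TLR1 (-1.01 ± 0.11). OR51B4 overlaps other annotated genes, so its reads are uncertain.

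With Dox present, 21 rose and 0 fell (24 and 0 over the list alone) of 29 nucleolar genes, including WDR74 (0.72 ± 0.06), RRP9 (0.63 ± 0.07) and NOP56 (0.49 ± 0.06). The list test gave adjusted p = 4.99e-14, and adjusted p = 0.0507 with an estimated correlation. Of the nucleotide and polyamine synthesis genes 8 rose and 2 fell (9 and 3 over the list alone), with IMPDH1 at 0.90 ± 0.06 and UMPS at 0.40 ± 0.06. The list test gave adjusted p = 0.00313, and adjusted p = 0.181 with an estimated correlation. Of the DNA replication genes 1 rose and 9 fell (1 and 12 over the list alone), with CCNE2 at -0.56 ± 0.06. Tested together, these had adjusted p = 0.00816, and adjusted p = 0.181 with an estimated correlation. Of the mitotic genes 0 rose and 13 fell (1 and 14 over the list alone), with KIF11 at -0.52 ± 0.07 and TOP2A at -0.42 ± 0.06. It had adjusted p = 2.95e-04, and adjusted p = 0.181 with an estimated correlation. Of the immediate early genes 1 rose and 12 fell (2 and 12 over the list alone), including MCL1 (-0.47 ± 0.05). Tested together, these had adjusted p = 0.00155, and adjusted p = 0.181 with an estimated correlation. Of the YAP and TEAD targets 1 rose and 10 fell (1 and 12 over the list alone), with ANKRD1 at -0.95 ± 0.07 and CCN1 at -0.38 ± 0.06. The list had adjusted p = 6.10e-04, and adjusted p = 0.181 with an estimated correlation. Of the interferon-stimulated genes 0 rose and 6 fell (0 and 7 over the list alone), with IFI44 at -0.57 ± 0.07. Its test gave adjusted p = 0.0322, and adjusted p = 0.273 with an estimated correlation. Of the hypoxia and glycolysis genes 6 rose and 2 fell (8 and 2 over the list alone), with HK2 at 0.99 ± 0.06 and VEGFA at 0.61 ± 0.08. As a list it had adjusted p = 0.0271, and adjusted p = 0.181 with an estimated correlation. No cytosolic ribosomal protein gene passed the test in this background, neither over all genes nor over the list alone (0 of 49, adjusted p = 0.0552). After rescaling the list passed as higher (adjusted p = 0.0397), while on the deposited scaling it had adjusted p = 0.791 with an estimated correlation. Of the cholesterol genes 3 rose and 6 fell (3 and 6 over the list alone), with SQLE at 0.43 ± 0.06 and STARD4 at -0.83 ± 0.10, and the list did not pass (adjusted p = 0.610). Median and test of the adrenergic list differed in sign.

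Effects of OHT_Dox against Dox correlated with GC content across genes (Spearman 0.295 over 18673 genes, which are not independent replicates), and OHT_Dox replicate 3 had the highest correlation of its deviations with GC content among the 12 libraries (0.461). Without Dox replicate 1 and OHT_Dox replicate 3, a pair chosen after the data were seen, 1404 genes rose and 1576 fell.

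**Figure D2:**
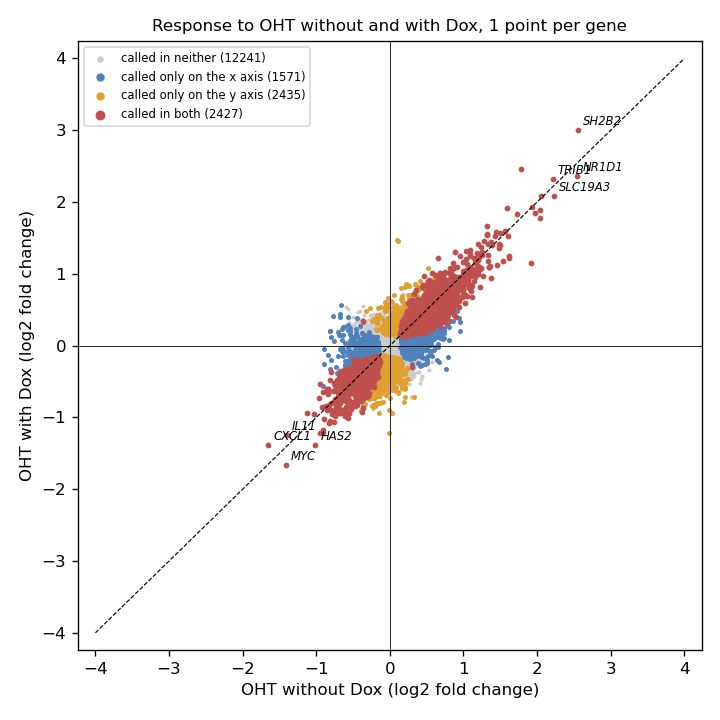
Log2 fold change with OHT in the presence of Dox (y axis) against that in its absence (x axis), 1 point per gene tested, coloured by whether the gene passed the test on neither axis, on 1 axis or on both. Of the genes called on both axes 1514 rose and 911 fell on both.

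Between these backgrounds, which share no library, the OHT effects correlated across genes with Pearson's 0.690 and Spearman's 0.543, where genes are not independent replicates. Of the 3998 genes called without Dox, 3633 (90.9%) had the same sign with Dox, 1514 rose in both (272 if the calls were independent), 911 fell in both (238 if independent) and 2 went opposite ways. The slope of the response with Dox on that without was 1.07 (SE 0.102, 95% jackknife interval 0.872 to 1.27, 6362 genes), so a response of the same size lies within the interval.

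The comparison of Dox with Ctrl asks what the hairpin does without OHT, and Dox itself has no separate control in the design. SNAI2 (ENSG00000019549), a transcriptional repressor of epithelial genes, fell from 9.44 ± 0.63 to 3.61 ± 0.57 CPM (-1.28 ± 0.12, adjusted p = 4.16e-06). THBS1 (ENSG00000137801), a matrix glycoprotein, fell from 978 ± 74 to 485 ± 25 CPM (-1.01 ± 0.07). COL6A3 (ENSG00000163359), a collagen chain, fell from 26.9 ± 2.4 to 11.4 ± 1.1 CPM (-1.21 ± 0.11). TGFBI (ENSG00000120708), a TGF-beta-induced matrix protein, fell from 174 ± 9.0 to 88.9 ± 4.9 CPM (-0.97 ± 0.08). TRIM55 (ENSG00000147573), a muscle-type ubiquitin ligase, rose from 114 ± 17 to 223 ± 15 CPM (0.97 ± 0.09). SLC41A2 (ENSG00000136052), a magnesium transporter, rose from 13.7 ± 0.15 to 27.7 ± 1.3 CPM (0.98 ± 0.08). The largest rise was in reads assigned to MIR30A (ENSG00000207827), with 4 to 9 reads in the libraries without Dox and 1207 to 1709 in those with it (5.60 ± 0.12). The overlapping LINC00472 went from 9.63 to 142 CPM. The other large falls were LSM6 (-1.15 ± 0.09, ENSG00000164167), DIRAS3 (-1.002 ± 0.11), PADI1 (-0.98 ± 0.15), PMEPA1 (-0.89 ± 0.08, ENSG00000124225) and SORBS2 (-0.84 ± 0.08). The other large rises were UNC5C (0.98 ± 0.11), C21orf91 (0.86 ± 0.09), its overlapping transcript C21orf91-OT1 (0.77 ± 0.09), LNCOG (0.72 ± 0.16), GCH1 (0.67 ± 0.13), SAMD9 (0.66 ± 0.11) and GBP3 (0.64 ± 0.11). LNCOG was not called without Ctrl replicate 3, Dox replicate 2 or Dox replicate 3 (0.70, 0.70 and 0.63).

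In total 1061 genes rose and 487 fell, 1548 of 18674 (8.29%), and 5 rises and 11 falls exceeded 2-fold. Trimmed-mean rescaling moves genes well above the pseudocount by -0.053 and genes near it by less. After it 515 rose and 746 fell, and all 487 falls but only 515 of the 1061 rises of the deposited scaling were kept. Rises and falls came to 2274 and 906 without Ctrl replicate 1, 152 and 199 without Ctrl replicate 2, 109 and 122 without Ctrl replicate 3, 597 and 264 without Dox replicate 1, 85 and 112 without Dox replicate 2, and 392 and 217 without Dox replicate 3. The Dox effects correlated across genes with transcript length (Spearman 0.261) and GC content (-0.307), and after each library's trend with these was removed 374 rose and 742 fell.

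Members of the matrix, TGF-beta and ribosomal protein lists fell with Dox in the absence of OHT. Of 25 extracellular matrix genes, 1 rose and 10 fell (3 and 12 over the list alone), including COL1A1 (-0.71 ± 0.07), COL5A1 (-0.62 ± 0.07) and SPARC (-0.46 ± 0.05), while LAMC1 rose (0.32 ± 0.07). It had adjusted p = 5.90e-07, and adjusted p = 0.283 with an estimated correlation. Of 20 TGF-beta response genes, 0 rose and 7 fell (1 and 9 over the list alone), including BHLHE40 (-0.59 ± 0.12) and TGFB2 (-0.36 ± 0.10). The list had adjusted p = 6.90e-06, and adjusted p = 0.0789 with an estimated correlation. Of the epithelial and haematopoietic markers 0 rose and 2 fell (0 and 2 over the list alone) of 5, the keratins KRT18 (-0.58 ± 0.05) and KRT8 (-0.51 ± 0.06). Its test gave adjusted p = 6.05e-04, and adjusted p = 0.0789 with an estimated correlation. Of the mesenchymal markers 2 rose and 3 fell (5 and 3 over the list alone) of 22, with VIM (-0.30 ± 0.06) and CD44 (-0.21 ± 0.05) falling beside SNAI2 and NT5E rising (0.22 ± 0.05), which did not pass as a list (adjusted p = 0.630). After rescaling 0 mesenchymal markers rose and 3 fell. Of the cytosolic ribosomal protein genes 0 rose and 12 fell (0 and 37 over the list alone), with RPS3 at -0.31 ± 0.07 and RPS19 at -0.30 ± 0.07. The list test gave adjusted p = 4.57e-21, and adjusted p = 0.284 with an estimated correlation. Of the nucleolar genes 1 rose and 4 fell (2 and 6 over the list alone), with FBL at -0.26 ± 0.06 and POLR1A at 0.24 ± 0.07. Tested together, these had adjusted p = 0.00193, and adjusted p = 0.297 with an estimated correlation. No cholesterol gene passed the test, 0 over all genes and 0 over the list alone, with MVD at -0.35 ± 0.11 and HMGCS1 at -0.26 ± 0.09. After rescaling 0 of them rose and 4 fell. The list was lower with adjusted p = 9.21e-04, and adjusted p = 0.380 with an estimated correlation. Of the YAP and TEAD targets 5 rose and 0 fell (7 and 1 over the list alone), with AMOTL1 at 0.37 ± 0.07 and F3 at 0.48 ± 0.13. It had adjusted p = 0.0369, and adjusted p = 0.370 with an estimated correlation. It did not pass after rescaling (adjusted p = 0.0549), where 2 members rose and 1 fell.

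Further lists passed for Dox without OHT with few called members. One was genes described as MYC-repressed, of which 0 rose and 1 fell (0 and 1 over the list alone), the fall being THBS1. The list had adjusted p = 0.0258, and adjusted p = 0.185 with an estimated correlation. Heat shock genes were another, of which 1 rose and 1 fell (2 and 4 over the list alone), with HSPA1B at -0.53 ± 0.09 and HSPA4L at 0.34 ± 0.07. Its test gave adjusted p = 0.0378, and adjusted p = 0.284 with an estimated correlation. Endoplasmic reticulum stress genes passed too, of which 1 rose and 0 fell (0 and 0 over the list alone), the rise being DNAJC3 at 0.23 ± 0.07 although the list leaned down. As a list it had adjusted p = 0.0492, and adjusted p = 0.370 with an estimated correlation. Of the 37 pausing and elongation factor genes 5 rose and 0 fell (8 and 0 over the list alone), with AFF1 at 0.46 ± 0.10, CCNT2 at 0.37 ± 0.09 and AFF4 at 0.43 ± 0.10, and the list did not pass (adjusted p = 0.336). After rescaling 3 of them rose and the list's median changed sign. Of the immediate early genes 1 rose and 3 fell (6 and 5 over the list alone), with KLF6 at -0.56 ± 0.07, MYC at -0.44 ± 0.10 and DUSP5 at 0.31 ± 0.07. That list did not pass (adjusted p = 0.330), and its test leaned down while its median and mean were above 0. No DNA replication or mitotic gene passed over all genes, and 5 mitotic genes rose when adjusted over the list alone. The mitotic median changed sign on rescaling, and median and mean of the DNA replication list differed in sign, as did those of the mesenchymal list.

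The comparison of OHT_Dox with OHT asks what the hairpin does with OHT. THBS1 fell from 938 ± 99 to 413 ± 25 CPM (-1.18 ± 0.07, adjusted p = 4.28e-09), COL6A3 by -1.14 ± 0.11, SNAI2 by -1.09 ± 0.12 and LSM6, a U6 small nuclear RNA-binding protein gene, by -1.14 ± 0.09. INSIG1 (ENSG00000186480), a sterol sensor, fell from 113 ± 35 to 40.8 ± 1.8 CPM (-1.42 ± 0.20, adjusted p = 2.73e-04), with a wide spread in OHT, and was not called with robust moderation. PFKFB4 (ENSG00000114268), a regulator of glycolysis, fell from 19.4 ± 2.1 to 9.15 ± 1.4 CPM (-1.05 ± 0.13) and RGS4 from 99.9 ± 1.7 to 48.3 ± 1.7 CPM (-1.04 ± 0.08). TRIM55 rose by 0.96 ± 0.09, SLC41A2 by 0.75 ± 0.08, CSRP1 (ENSG00000159176), a LIM-domain protein gene, by 0.64 ± 0.08 and TAGLN (ENSG00000149591), an actin-binding protein gene, by 0.61 ± 0.08. MIR30A rose by 5.62 ± 0.12. In total 95 genes rose and 297 fell, 392 of 18674 (2.10%), and 6 rises and 16 falls exceeded 2-fold. Rises and falls came to 162 and 518 with DESeq2 and to 175 and 518 after removal of the trend with transcript length and GC content. Rises came to 41 without OHT replicate 1, 48 without OHT replicate 2, 32 without OHT_Dox replicate 1, 42 without OHT_Dox replicate 2 and 53 without OHT_Dox replicate 3. Falls came to 155 without OHT replicate 1 and 172 without OHT_Dox replicate 1.

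The other large rises were GALNT16 (0.85 ± 0.14), ATOH8 (0.75 ± 0.17), UNC5C (0.58 ± 0.11), FGF1 (0.59 ± 0.08) and SPRY4-AS1 (0.56 ± 0.07). The annotations of the last of these and FGF1 overlap on opposite strands, so their reads are uncertain. The other large falls were SLCO5A1 (-1.04 ± 0.24) and IL21R-AS1 (-1.01 ± 0.22), which is antisense to IL21R. SLCO5A1 was not called with robust moderation or without OHT replicate 1, OHT replicate 3 or any of the OHT_Dox libraries. IL21R-AS1 was not called without OHT replicate 1 or 2 or OHT_Dox replicate 1 or 2, nor ATOH8 without OHT replicate 1 or OHT_Dox replicate 2 or 3.

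Of the cholesterol synthesis and uptake genes 0 rose and 12 fell (0 and 17 over the list alone) of 21 with Dox in the presence of OHT, including HMGCS1 (-0.65 ± 0.09), IDI1 (-0.69 ± 0.11) and SQLE (-0.32 ± 0.06). As a list it had adjusted p = 9.43e-22, and adjusted p = 0.0973 with an estimated correlation. Of the extracellular matrix genes 0 rose and 9 fell (1 and 13 over the list alone), with COL1A1 at -0.72 ± 0.07, COL5A1 at -0.72 ± 0.07 and FN1 at -0.52 ± 0.09. The list test gave adjusted p = 1.56e-15, and adjusted p = 0.0883 with an estimated correlation. Of the TGF-beta response genes 2 rose and 9 fell (4 and 9 over the list alone), with PMEPA1 at -0.996 ± 0.08, TGFBI at -0.82 ± 0.08 and BHLHE40 at -0.86 ± 0.12 falling and TAGLN rising. Tested together, these had adjusted p = 4.76e-04, and adjusted p = 0.0973 with an estimated correlation. Of the epithelial and haematopoietic markers 0 rose and 2 fell (0 and 2 over the list alone), again KRT18 (-0.45 ± 0.05) and KRT8 (-0.41 ± 0.06). The list test gave adjusted p = 3.11e-04, and adjusted p = 0.0743 with an estimated correlation. In the mesenchymal list 0 rose and 1 fell (0 and 5 over the list alone), the fall being SNAI2. It passed with adjusted p = 6.38e-04, and adjusted p = 0.201 with an estimated correlation. In the histone list 1 rose and 0 fell (1 and 0 over the list alone), the rise being H2BC12 at 0.54 ± 0.08. It passed with adjusted p = 0.0203, and adjusted p = 0.0973 with an estimated correlation. In the TCEAL and BEX list 0 rose and 1 fell (0 and 1 over the list alone), the fall being TCEAL9 at -0.56 ± 0.08. It passed with adjusted p = 0.0201, and adjusted p = 0.201 with an estimated correlation. In the RNA polymerase II subunit list 0 rose and 0 fell (1 and 0 over the list alone), with POLR2A at 0.26 ± 0.08. It passed with adjusted p = 0.0434, and adjusted p = 0.314 with an estimated correlation and did not pass after rescaling (adjusted p = 0.0726). Of the immediate early genes 1 rose and 3 fell (2 and 5 over the list alone), with KLF6 at -0.62 ± 0.07, MYC at -0.70 ± 0.10 and EGR1 at 0.52 ± 0.10, and that list did not pass (adjusted p = 0.486). No pausing and elongation factor gene passed the test over all genes or over the list alone. The same held for the 49 cytosolic ribosomal protein genes, whose list did not pass (median 0.031, adjusted p = 0.542). It held too for the 18 YAP and TEAD targets (median 0.063, adjusted p = 0.627). Median, mean and test differed in sign for the heat shock, interferon, immediate early and hypoxia lists.

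**Figure D3:**
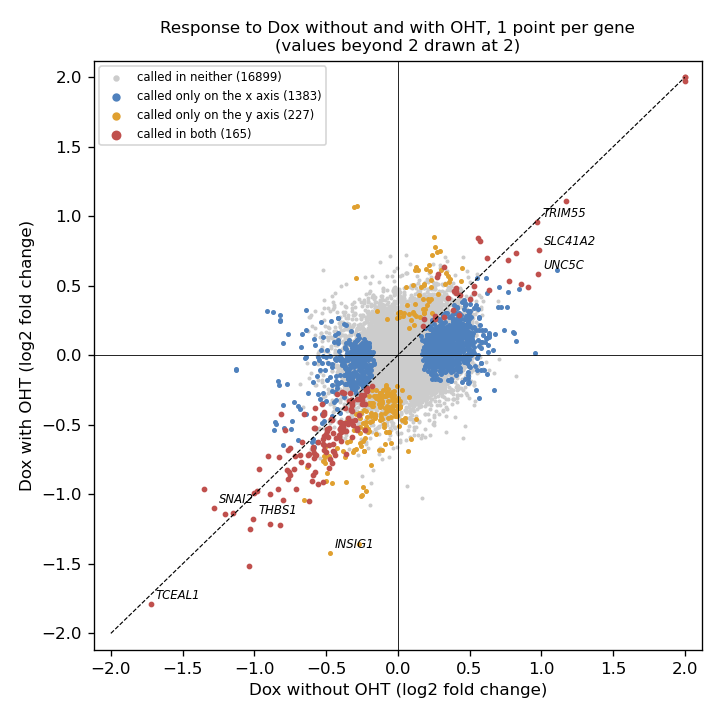
Log2 fold change with Dox in the presence of OHT (y axis) against that in its absence (x axis), 1 point per gene tested with values beyond 2 drawn at 2, coloured by whether the gene passed the test on neither axis, on 1 axis or on both. Of the genes called on both axes 35 rose and 130 fell on both.

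The Dox effects without and with OHT, which share no library, correlated across genes with Pearson's 0.366 and Spearman's 0.207. Their trends ran opposite ways, with Spearman 0.261 without and -0.091 with OHT for transcript length, and -0.307 and 0.161 for GC content. How far these trends lower the agreement was not tested. Of the 1548 genes called without OHT 1112 (71.8%) had the same sign with OHT, 35 rose in both (5.40 if independent), 130 fell in both (7.75 if independent) and 0 went opposite ways. The slope of the response with OHT on that without was 0.996 (SE 0.161, 95% jackknife interval 0.680 to 1.31, 1521 genes). The ratio of medians was 0.784. Without Ctrl replicate 1 the slope was 0.780 and the ratio of medians 0.444. Without MIR30A, LINC00472 and ENSG00000269966, left out after the data were seen, the slope was 0.988.

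**Figure D4:**
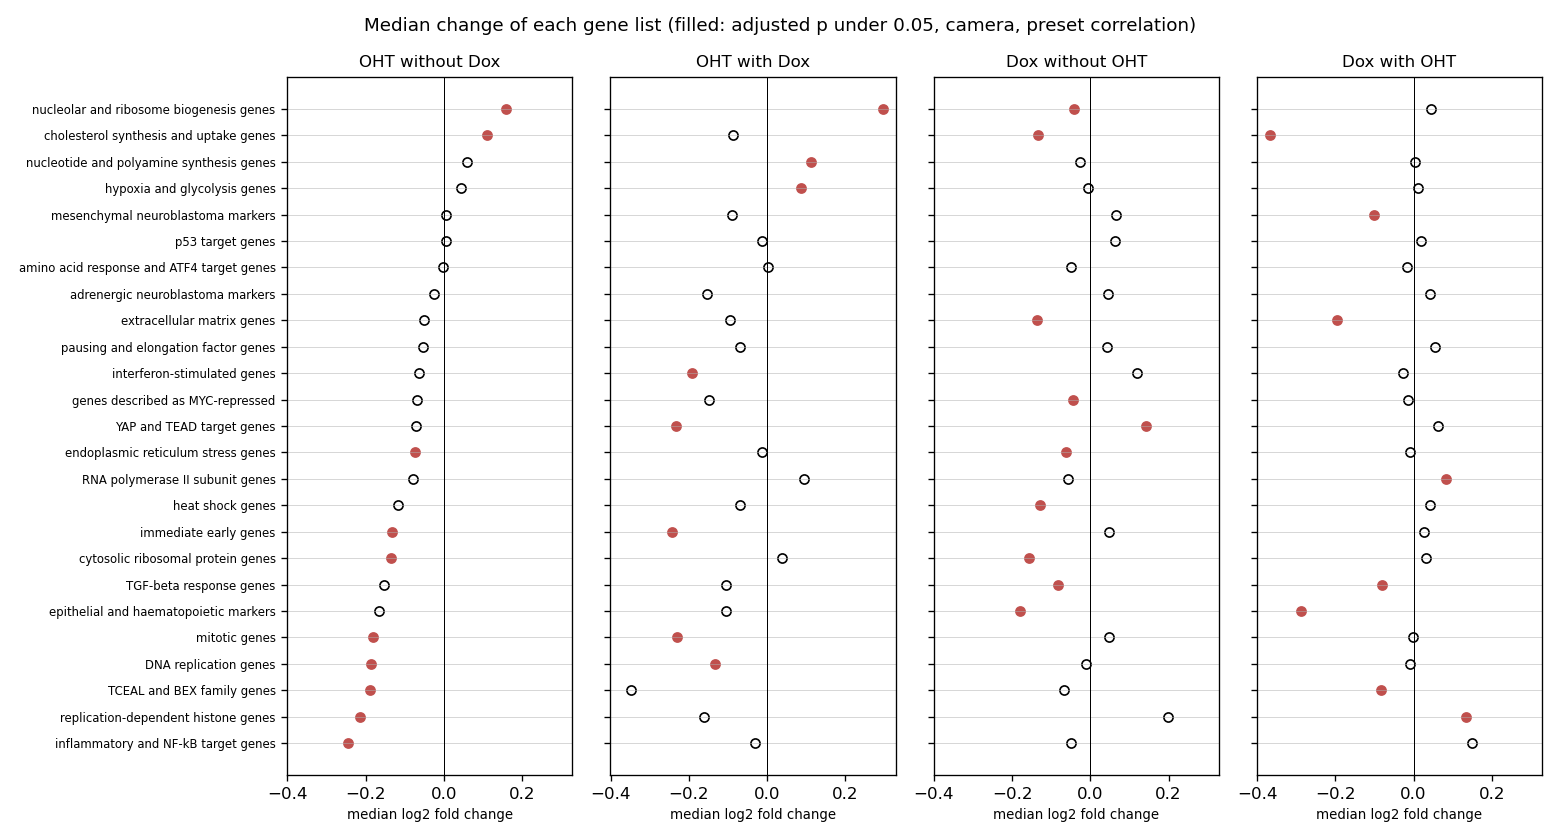
Median log2 fold change (x axis) of the measured members of each gene list (y axis) in the 4 comparisons (panels), filled where the adjusted p of camera with the preset correlation was under 0.05. No filled list passed with an estimated correlation, and the nucleolar list stands at 0.16 for OHT without Dox and 0.30 for OHT with Dox.

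Whether the response to OHT differs with the hairpin was tested by the interaction. No gene passed with limma (0 calls, 2879 of 18674 at an unadjusted p under 0.05, smallest adjusted p = 0.221) or with edgeR (0 calls, 2710 unadjusted). With DESeq2 1 passed (2761 unadjusted), DAXX, which encodes a histone chaperone, at 0.77 (adjusted p = 8.73e-04). Without Ctrl replicate 1 limma called 1041 genes. The interaction effects correlated across genes with transcript length (Spearman -0.298) and GC content (0.383). After removal of these trends 6 lists passed, and the medians of the 5 lists below were 0.121, 0.178, 0.109, -0.226 and 0.220 in the order given. Among the lists, nucleolar genes had a median interaction of 0.138 (adjusted p = 5.58e-05, and adjusted p = 0.431 with an estimated correlation), with WDR74 at 0.39 ± 0.09 and FBL at 0.26 ± 0.09. The ribosomal protein list stood at 0.175 (adjusted p = 8.87e-20, and adjusted p = 0.440 with an estimated correlation), with RPLP2 at 0.32 ± 0.08 and RPL32 at 0.30 ± 0.09. Its median was -0.136 for OHT without Dox and -0.158 for Dox without OHT, falls that rest on the same Ctrl libraries. For OHT with Dox the median was 0.038 and for Dox with OHT 0.031. The RNA polymerase II subunit list stood at 0.142 (adjusted p = 0.00147, and adjusted p = 0.431 with an estimated correlation), with POLR2F at 0.32 ± 0.09 and POLR2L at 0.32 ± 0.10. The cholesterol list stood at -0.232 (adjusted p = 1.78e-05, and adjusted p = 0.728 with an estimated correlation), with INSIG1 at -0.95 ± 0.28 and STARD4 at -0.59 ± 0.15. The inflammatory list stood at 0.181 (adjusted p = 0.0187, and adjusted p = 0.440 with an estimated correlation), with RELB at 0.31 ± 0.11. Counts adjusted over the list alone were 1 higher nucleolar gene, 10 higher ribosomal protein genes, 5 higher polymerase subunit genes and 7 lower cholesterol genes, against 0 over all genes in each.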

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

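The tests weighed here against the list interactions were written after the result was seen. The median interaction was 0.1379 for nucleolar and ribosome biogenesis genes, 0.1747 for cytosolic ribosomal protein genes, -0.2318 for cholesterol genes, 0.1810 for inflammatory genes and 0.1421 for RNA polymerase II subunit genes. Spread between libraries could give such medians, so the residuals of an additive fit were permuted over the libraries in 100 tables, the real one included. A median as far from 0 came in 13 tables for cholesterol genes (highest other 0.372) and in 5 for polymerase subunit genes (highest other 0.177), so spread stays open for these. It came in 3 for ribosomal protein genes (highest other 0.206), 3 for inflammatory genes (highest other 0.194) and 1, the real one, for nucleolar genes (highest other 0.131), shares that are not adjusted for the choice of these lists because they passed. Residuals of a fit are also narrower than the spread between libraries, so these shares may be too small and do not exclude spread. A different response to OHT under the hairpin stays an open explanation, and each list lost its call with an estimated correlation.

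Over all genes rather than the lists, 7 of the 100 tables had as many genes at an unadjusted interaction p under 0.05 as the 2879 seen, and the highest other had 4237. Without Ctrl replicate 1 the interaction had 1041 calls, against 0 with it.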

How the results depend on the processing

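Counts for Dox without OHT moved most, and for every change below the cause was not tested. Rises and falls, 1061 and 487, became 674 and 318 with no filter, 515 and 746 after rescaling, 515 and 804 with edgeR, 374 and 742 after removal of the length and GC trend, and 2580 and 1106 without Ctrl 1 and OHT_Dox 3, and DESeq2 called 1171 falls. With 1 library left out they ran from 85 to 2274 rises and from 112 to 906 falls. For Dox with OHT, 95 rises and 297 falls became 162 and 518 with DESeq2 and 175 and 518 after trend removal, rises 57 with no filter and 59 without Dox 1 and OHT_Dox 3, and with 1 library left out 32 to 67 rises and 155 to 251 falls. With the replicate number as a block, Dox without OHT gave 1767 and 758 and Dox with OHT 171 and 460. The numbers do not pair samples by any label, and a hint of pairing comes from the data alone, where 9 of 12 libraries correlated best with their own number and same-number correlations ran from -0.174 to 0.330. For OHT without Dox 2357 rises and 1641 falls became 2434 and 2520 after trend removal, and for OHT with Dox 1404 rose and 1576 fell without Dox 1 and OHT_Dox 3. Interaction calls ran from 0 to 1041 with 1 library left out, and were 1 with DESeq2 and 1 without Ctrl 1 and OHT_Dox 3. Lists passing, 10, 8, 10 and 8 in the 4 comparisons and 5 for the interaction, became 0 in each with an estimated correlation. The fry test, which asks a different question, did not follow camera throughout. For OHT without Dox it passed the nucleolar list (adjusted p = 2.26e-04) and the nucleotide list (adjusted p = 4.25e-04), but not the cholesterol list (adjusted p = 0.0961). For the interaction no list passed fry (lowest adjusted p = 0.264). For Dox without OHT they were 6 with no filter and 6 to 12 with 1 library left out. The OHT slope was 0.965 without Ctrl 1 and OHT_Dox 3. The Dox slope was 0.784 as a ratio of medians, 0.776 without Ctrl 1 and OHT_Dox 3, and 0.780 to 1.09 with 1 library left out. Of 1982 named-gene values 1948 kept their call status, 25 lost a call, 9 gained one and 0 changed sign with a call in either fit. A change of sign without a call in either fit counted as kept, and most named genes were chosen for large called changes. Depth limits genes of a few reads, since 1 read is 0.0225 CPM in the shallowest library, OHT_Dox 3.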

Other observations

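The tests of the microRNA seed and of the length and GC trend were written before their results were seen, and the tests of scaling, of the MIR30A reads and of the splits only after.

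Reads over the MIR30A host region rose with Dox in both OHT states. LINC00472 went from 9.634 to 141.9 CPM without OHT and from 9.325 to 142.8 CPM with OHT, and ENSG00000269966 from 125.8 to 283.9 CPM without OHT. OGFRL1, which overlaps the host annotation, changed by 0.28 without OHT (adjusted p = 0.0171) and by 0.12 with OHT (adjusted p = 0.463). MIR30C2, another member of the family, had 0 to 6 reads per library. ENSG00000257522, which does not overlap the host region, also rose. It lay at 2.44 to 2.77 CPM in Ctrl and 11.7 to 13.7 CPM in Dox. With OHT it lay at 3.02 to 3.19 CPM in OHT and 13.5 to 13.9 CPM in OHT_Dox. The cause of its rise was not tested.

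More transcription of the endogenous host would keep the ratio of MIR30A to LINC00472 reads, but in the added reads it was at least 17.8 times the ratio without Dox, 0.210 to 0.231 against 0.0118. Reads from the induced hairpin cassette, if it carries miR-30a backbone sequence, could raise the genes that overlap it without the flanking ones. The highest log2 change among the genes that flank the host was 0.418, for KCNQ5-IT1, which did not pass the test, against a bound of 1.908. ENSG00000269966, which overlaps the host, rose by 1.17 without OHT and by 1.11 with OHT. The labels do not name the backbone, so this stays a candidate explanation.

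Genes that fell with Dox might do so through loss of TCEAL1, through Dox itself or through microRNA-like matches of the hairpin. Among the 16319 words scanned, GTAAGAT had the lowest z for Dox in both OHT states and was picked for that reason. Genes with this 3′ untranslated word were lower with Dox, with z = -8.89 without OHT and z = -8.70 with OHT against a limit of 4.67. The mean differences were only -0.041 and -0.040 log2. For OHT the same scan gave z = 0.93 without Dox and z = 1.062 with Dox, although the lowest z of any word for OHT without Dox, -5.31, also passed the limit. Only 2 words passed the limit in both OHT states, GTAAGAT and TAAGATA, which overlap and so are not separate findings. Both occur in the TCEAL1 transcript, as do 8.97% of the words scanned. LSM6, THBS1, SORBS2 and SLCO5A1 carry GTAAGAT, and SNAI2, COL6A3, DIRAS3, PADI1, TGFBI, PMEPA1, INSIG1, PFKFB4 and RGS4 do not. Without the genes that carry GTAAGAT, Dox gave 902 rises and 419 falls without OHT and 75 and 204 with OHT. Leaving genes out lowers such counts by itself. Without adjustment for region length, 75 of 246 falls of Dox with OHT carried GTAAGAT (30.5% against 9.35% of other genes, Fisher's exact p = 4.47e-20). The word was picked from these same Dox effects, so Fisher's p-values for the Dox calls do not test it independently. But 316 of 2326 falls of OHT with Dox carried GTAAGAT too (13.6% against 8.88%, Fisher's exact p = 3.49e-11). For Dox without OHT it was carried by 46 of 372 falls (12.4% against 9.70%, Fisher's exact p = 0.0919) and by 121 of 945 rises (12.8% against 9.52%, Fisher's exact p = 0.0017). With 1 hairpin and no separate control for Dox in the design, no single gene, with or without the word, can be assigned to any of these explanations.

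The excess of rises for Dox without OHT, 1061 against 487, could come from scaling or from a trend with transcript length and GC content. After removal of the trend 374 rises were called. After rescaling 40.84% of calls were rises. But rescaling moves genes down together, by -0.053 well above the pseudocount and by less near it. This swing follows from that shift and does not test scaling as the cause, which stays open. A biological excess of small rises also stays open, since removal of the trend would take out one that follows length or GC content.

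Splits of 3 against 3 libraries are too few to give a small p. Every other split also mixed treated and untreated libraries within both groups. The effects of treatment then entered the spread that the test uses, so few calls there could be foreseen and these splits decide little. The real grouping had the most calls, 1 of 10 splits, for OHT without Dox (3998, highest other 0), for OHT with Dox (4862, highest other 0), for Dox without OHT (1548, highest other 0) and for Dox with OHT (392, highest other 0).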
